A study of Mus musculus with 28 samples.

How the data were processed

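PolyA RNA from frontal cortex of Q331K knock-in and wild-type mice aged 20 months was sequenced in 28 libraries. Per the labels' protocols, tissue was snap frozen, RNA was extracted with TRIsure and an RNeasy kit, and libraries were made with Illumina's stranded mRNA kit with a shortened fragmentation. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.3, aligned with HISAT2 2.0.5 and placed on GRCm38. The counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited values are raw read counts per gene for each library, whole numbers that the authors did not normalise, as the values themselves show. Because the strand setting is open, reads of a gene cannot be told apart from those of an overlapping gene on the other strand. Of the genes named, exons of Tardbp, Atxn2, Pigk, Ano3, Csf1r, Gpr17, Matn4, Cox6a2, Rpl31, Junb, Dnaja1, Hnrnpk, Glul and Grn overlap a protein-coding neighbour on the other strand in GENCODE vM21, and their values are uncertain to that extent.

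The table held 25965 rows for 25900 gene identifiers. The 57 genes that filled several rows (122 rows) were summed per identifier. Each of the 28 value columns matched the title of 1 library. Names follow the deposited table, and 24987 identifiers also had a name in the reference. Groups were taken from the genotype in the titles. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom among 378 pairs was 6.37 over 15105 genes.

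Genes were filtered with filterByExpr, which left 16110, and libraries were scaled by TMM. Differences were tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest with robust dispersion, two-sided) in 1 fit of all 28 libraries with a mean per genotype and no covariate, since tissue, age and protocol were shared. Contrasts were HOM against WT, HET against WT, HOM against HET, and HOM plus WT minus 2 times HET for departure from a straight line. A separate fit tested a slope on the number of alleles (0, 1, 2). P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and 0.05 was the threshold. Fold changes are given on the log2 scale with the standard error from the same fit, and levels as CPM with the SD between libraries.

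Before the data were examined, 36 gene lists were fixed for cell types, neighbouring tissues, stress and metabolic pathways, and genes tied to TDP-43. Each was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and with an estimated correlation and fry beside it, adjusted over the lists. An exact permutation test of each list's mean log2 CPM was added after the data were examined, with 100000 resamples where both groups had 10 libraries. The rule for named genes was also fixed beforehand. It takes Tardbp, Mapt, Pvalb, Sort1 and Atxn2, then up to 12 called genes in each direction with the smallest p and a mean of at least 1 CPM, leaving out clone-like names. It adds up to 4 members of each list that passed camera, at most 2 of other lists, and the 3 called genes with the smallest p in each direction of the slope test, whatever their names. The text prints part of the list members this names, selected after their values were seen, and a few members are not reported here.

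Total counts of 30.5 to 74.9 M per library (median 53.55 M) set the precision, together with a biological coefficient of variation of 8.46%. On counts simulated for HOM against WT the fit recovered 88% of genes changed 1.6-fold and 59.2% of those changed 1.3-fold, with 5 false among 147 calls (16057 genes). For HET against WT, where a gene had the square root of its HOM fold, it recovered 68% and 30.6% of the same genes. The simulation changed 49 or 50 genes at each fold, up to 2.5-fold, and drew each gene independently. Neither these shares nor the false calls can be carried over to the real tests, where genes were correlated and few changes were large. Alternatives were DESeq2 1.42.0, its size factors within edgeR, no count filter, a filter of 1 CPM in 8 libraries, limma voom with quality weights, 2 surrogate variables from sva 3.50.0, only the groups compared, the replicate number as a block, and each library left out in turn. Alternatives without the shallowest or the outlying libraries and with marker scores as covariates were added after the data were examined. The overlap of responses was compared with 100 simulated draws that permuted residuals among libraries. Library totals and the genes named were also checked for single outlying libraries.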

Results

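Transcripts of the frontal cortex were measured by polyA RNA sequencing in 28 libraries from mice aged 20 months on the C57BL/6 background. The mice carried 0, 1 or 2 copies of a knock-in allele of Tardbp, the gene of the RNA-binding protein TDP-43, that encodes the Q331K substitution known from amyotrophic lateral sclerosis (ALS). There were 8 wild-type (WT), 10 heterozygous (HET) and 10 homozygous (HOM) libraries. The total count per library, with M for 1e6 reads, ran from 46.5 to 64.1 M in WT, from 45 to 74.9 M in HET and from 30.5 to 62.6 M in HOM, with HOM 2 at 30.5 M and HOM 1 at 32.8 M. The labels do not give sex, litter or batch. All 28 libraries held the Y-linked transcript Ddx3y, at 60.2 to 73 CPM, and at most 0.258 CPM of Xist, the pattern of male tissue. The labels number the libraries as separate samples without saying that each came from its own animal, so p-values measure the spread between these libraries, which may be technical in part.

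Tardbp itself (ENSMUSG00000041459, minus strand of chromosome 4, 148612382 to 148627019, GRCm38) was higher in HOM than in WT. It stood at 321 ± 13.6 CPM in WT (SD, n = 8), 328 ± 13.3 in HET (n = 10) and 349 ± 18.9 in HOM (n = 10). All 10 HOM libraries lay above the WT mean and 7 lay above the highest WT library. The log2 fold change of HOM over WT was 0.12 (SE 0.03, adjusted p = 0.0185, edgeR quasi-likelihood test), a fold of 1.09. The counts do not separate the alleles, so they do not check the genotype labels, and exons of Tardbp overlap those of Masp2 on the other strand.

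**Figure D1:**
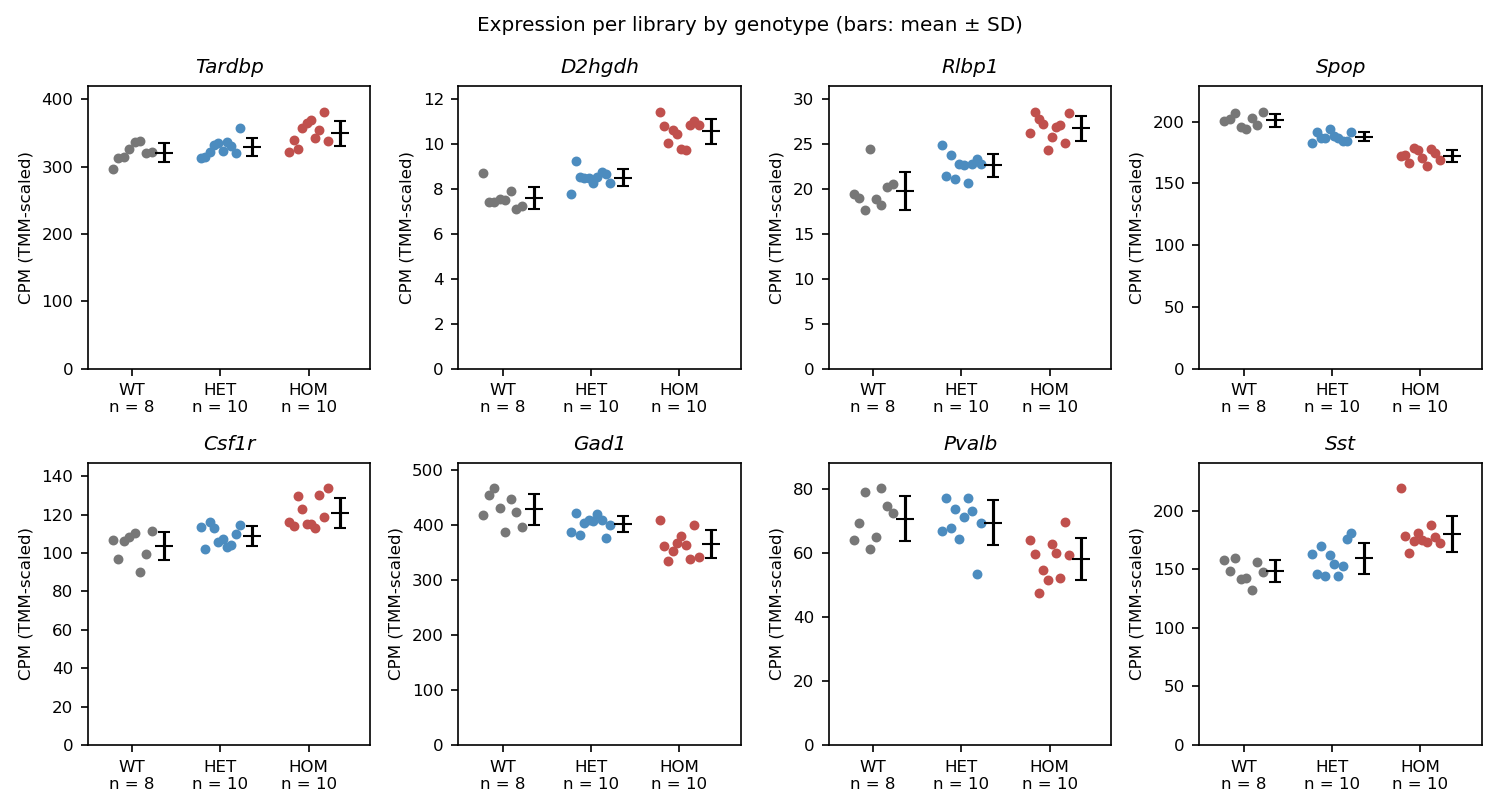
Expression in CPM (TMM-scaled, y axes from 0) of 8 genes in each WT, HET and HOM library, with the mean and SD of each genotype drawn beside the points. Tardbp, D2hgdh, Rlbp1, Csf1r and Sst were higher in HOM than in WT, and Spop, Gad1 and Pvalb were lower.

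The comparison of HOM with WT asks what 2 mutant alleles change in aged cortex. The genes that rose with the smallest p were D2hgdh, which encodes the mitochondrial D-2-hydroxyglutarate dehydrogenase, and Rlbp1, a retinaldehyde-binding protein. D2hgdh rose from 7.61 ± 0.498 CPM in WT (n = 8) to 10.6 ± 0.557 in HOM (n = 10), a fold of 1.39, and all 10 HOM libraries lay above every WT library. Rlbp1 rose from 19.8 ± 2.1 to 26.8 ± 1.41 CPM. The astrocyte gap junction gene Gja1 rose by 0.21 on the log2 scale, the cystathionine beta-synthase gene Cbs by 0.47, the integrin gene Itgb5 by 0.27 and the moesin gene Msn by 0.25. Tifab, Scrg1, Ptpn13, St6galnac2, Synrg and Ecm1 completed the 12 with the smallest p, between 0.15 and 0.47.

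The genes that fell with the smallest p included Spop, an adaptor of a cullin-3 ubiquitin ligase, which went from 201 ± 5.1 CPM in WT (n = 8) to 172 ± 4.86 in HOM (n = 10), below every WT library in all 10. Lsamp, a neuronal adhesion gene, had a log2 fold change of -0.21, the Rag GTPase gene Rragd -0.24, the secretory chaperone gene Scg5 -0.21, the mitochondrial superoxide dismutase gene Sod2 -0.17 and the neuregulin receptor gene Erbb4 -0.28. Pigk, Zrsr2, Tshz2, Ica1, Ano3 and Olfr316 were the others of the 12, between -0.15 and -0.96. Olfr316 averaged 2.23 CPM in WT and 1.14 in HOM, belongs to a large family of similar genes, and its identifier is not in the reference annotation used here. The smallest p of all belonged to a gene outside the naming rule of this comparison and chosen after its values were seen, 4933439F18Rik (reference name Gid4, a substrate receptor of another ubiquitin ligase). It went from 79.6 ± 2.45 CPM in WT (n = 8) to 58.8 ± 2.08 in HOM (n = 10), a log2 fold change of -0.44 (SE 0.02, edgeR adjusted p = 1.86e-13).

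Of 16110 genes tested, 1226 passed an adjusted p of 0.05 in HOM against WT by edgeR's quasi-likelihood test, 629 higher and 597 lower. The changes were small: 335 of these genes exceeded 1.2-fold and 62 exceeded 1.5-fold. The count depended on the WT libraries, at 595 without WT 6 and 725 without WT 2, and 509 without WT 6 and HOM 3, the ends of the first principal component. It was 393 with marker scores of 4 neighbouring tissues as covariates, a choice made after the data were examined. Mapt, Sort1 and Atxn2, 3 genes of interest in TDP-43 biology, did not pass (edgeR adjusted p = 0.664, 0.0825 and 0.756). That does not show that they were unchanged. For Mapt, 6 HOM libraries lay below the lowest WT library and 2 above the highest. For Sort1, 5 HOM libraries lay below the lowest WT library and 0 above the highest, and for Atxn2 3 and 0. Counts per gene do not show which exons were used, so splicing of these genes was not tested.

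Markers of microglia rose in HOM, with 12 of 23 tested members higher, 0 lower and 11 not past the threshold, and a median log2 fold change of 0.16. Csf1r, the receptor that maintains microglia, went from 104 ± 7.41 to 121 ± 7.74 CPM, and C1qc, Olfml3 and Tmem119 rose by 0.28, 0.30 and 0.34. With the mean scores of meningeal and endothelial markers as covariates, chosen after the data were examined, the HOM to WT difference in mean log2 CPM of the microglia list went from 0.164 ± 0.0378 (SE) to 0.0556 ± 0.0466. The precursor and parvalbumin lists were not put through that adjustment, so the same limit stays open for them. Oligodendrocyte precursor markers rose with a median of 0.17 and 5 of 13 members higher, among them Pdgfra (0.21), Ptprz1 (0.17), Gpr17 (0.30) and Matn4 (0.21). Endothelial and mural markers rose with a median of 0.16 and 7 of 24 higher, including Cdh5 (0.21), Itm2a (0.25), Myl9 (0.29) and Rgs5 (0.14). Mean log2 CPM of the list lay above the WT mean in 10 of 10 HOM libraries for each of these lists. The same held for the astrocyte and the choroid plexus markers, which did not pass exact permutation (adjusted p = 0.065 and 0.14). Exact permutation of the list means, a test added after the data were examined, over the 43758 splits of 8 WT and 10 HOM libraries, two-sided, gave adjusted p = 0.00576 for microglia, 0.00329 for precursors and 0.00603 for endothelial and mural markers. Camera with a preset correlation also passed all 3. That adds little, since it passed lists in all 99 other splits drawn of these WT and HOM libraries, up to 23 lists. The correlations estimated for the 3 lists were 0.37, 0.17 and 0.26, where the preset was 0.01. With these estimates camera gave adjusted p = 0.177, 0.13 and 0.293, and fry gave adjusted p = 0.00131, 0.00057 and 0.00907. Markers of meningeal fibroblasts, a tissue next to the cortex, stood higher in the same comparison, with a median of 0.59 and 2 of 18 past the threshold, Col1a1 (2.31 ± 0.668 to 4.01 ± 1.97 CPM) and Igfbp2 (0.34), and 17 adjusted over the list alone. Their adjusted p was 0.156 by exact permutation, and camera gave adjusted p = 0.624 with an estimated correlation. Adjusted over the list alone, 17 microglia, 6 precursor and 10 endothelial or mural genes were higher.

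**Figure D2:**
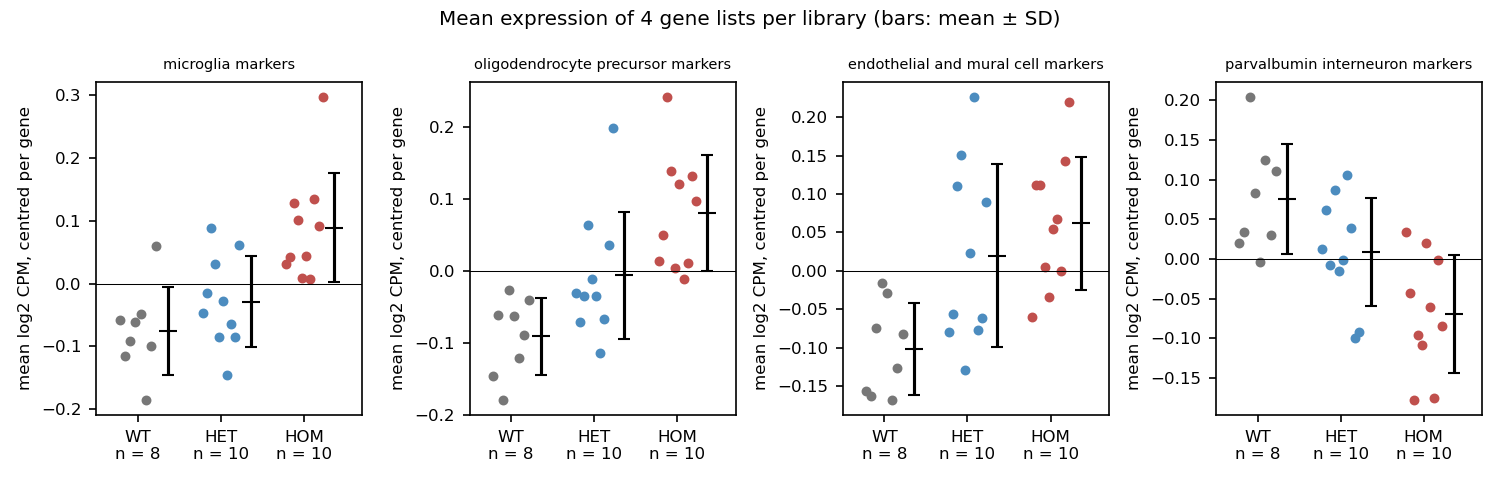
Mean log2 CPM of 4 gene lists in each library, each gene centred on its mean over all 28 libraries, with the mean and SD of each genotype. The microglia, precursor and vascular lists lay above the WT mean in 10 of 10 HOM libraries, and the parvalbumin list lay below it in 10 of 10.

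Markers of parvalbumin interneurons fell in HOM, with 3 of 11 members lower, 0 higher and a median of -0.21. Pvalb, the calcium-binding protein that defines these fast-spiking cells, went from 70.7 ± 7.08 to 58.1 ± 6.64 CPM (log2 fold change -0.28, SE 0.07, edgeR adjusted p = 0.0146). Erbb4 and the potassium channel gene Kcns3 (-0.24) also fell, and Cox6a2 had a log2 fold change of -0.30 (edgeR adjusted p = 0.0538). The list mean lay below the WT mean in 10 of 10 HOM libraries (exact permutation, adjusted p = 0.00617), and camera gave adjusted p = 0.13 with an estimated correlation. Fry gave adjusted p = 0.000839. The other interneuron markers went both ways: 2 of 28 were higher and 1 was lower, and 2 were higher and 2 lower adjusted over the list alone. Gad1, which makes GABA, went from 428 ± 27.6 to 365 ± 25 CPM, a log2 fold change of -0.23, while the neuropeptide gene Sst went from 148 ± 9.54 to 180 ± 15 CPM, 0.28 higher. Adjusted over the list alone, 5 parvalbumin markers were lower.

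Neuronal genes with long introns that are known to depend on TDP-43 had a median of -0.12, with 5 of 13 lower and 0 higher. Nrxn3 (-0.12), Nlgn1 (-0.14) and Grm8 (-0.20), all synaptic adhesion or receptor genes, fell. The list passed camera with the preset correlation (adjusted p = 0.000202) and fry (adjusted p = 6.07e-05). It reached adjusted p = 0.0554 by camera with an estimated correlation. It did not pass exact permutation, the test added after the data were examined (adjusted p = 0.125). Adjusted over the list alone, 7 were lower. The HET to WT difference in mean log2 CPM of the list was -0.0931 (exact permutation, adjusted p = 0.2), no smaller than the -0.0835 of HOM to WT. Among hnRNP and related RNA-binding proteins 5 of 28 were lower, with Hnrnpk at -0.09 and Ptbp2 at -0.12, and 1, Tardbp, was higher, against 7 and 1 adjusted over the list alone. That list passed camera with the preset correlation (adjusted p = 0.0394), and gave adjusted p = 0.624 with an estimated correlation and 0.349 by exact permutation. Of 34 genes linked to ALS and frontotemporal dementia, 4 were lower, among them Nek1 (-0.15) and 3110043O21Rik, the mouse ortholog of C9orf72 (-0.13), and 2 were higher, Tardbp and Grn. Adjusted over the list alone, 8 were lower and 3 higher. That list did not pass camera (adjusted p = 0.212).

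The remaining lists that passed camera with the preset correlation did not pass exact permutation. Astrocyte markers had a median of 0.10 with 4 of 21 higher, Aqp4 (0.28), Mlc1 (0.15), Glul (0.15) and Gja1, and 6 higher when adjusted over the list alone. Their adjusted p was 0.065 by exact permutation, 0.614 by camera with an estimated correlation and 0.0431 by fry. Reactive astrocyte genes had a median of 0.16 with 3 of 33 higher, among them Aspg (0.49) and Vim (0.38), and 3 adjusted over the list alone (adjusted p = 0.624 with an estimated correlation). HOM 3 carried part of this: without it the difference in mean log2 CPM of the list was 0.14 instead of 0.21, and Vim was no longer called (log2 fold change 0.25, edgeR adjusted p = 0.051). Disease-associated microglia genes had a median of 0.10 with 5 of 29 higher, among them Cd68 (0.20) and Lyz2 (0.38), and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.624 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.05 with 8 of 85 higher, among them Rpl31 (0.18) and Rps15 (0.13), and 16 higher and 2 lower adjusted over the list alone (adjusted p = 0.624 with an estimated correlation). Reads of these genes can be shared with pseudogene copies, so their values are uncertain, and without HOM 2 the difference in their mean log2 CPM was 0.03 instead of 0.05. Cholesterol synthesis genes had a median of -0.09 with 2 of 23 lower, Stard4 (-0.19) and Acat2 (-0.15), and 4 adjusted over the list alone (adjusted p = 0.624 with an estimated correlation). Immediate early genes, which follow neuronal activity, had a median of -0.22 and 0 of 25 past the threshold, with Egr2 at -0.54 and Junb at -0.38 (adjusted p = 0.659 with an estimated correlation). Heat shock genes had a median of -0.07 and 0 of 13 past the threshold, with Dnaja1 at -0.09 (adjusted p = 0.624 with an estimated correlation).

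Several lists did not pass camera. Synaptic genes had a median of -0.02 with 1 of 34 higher, the presynaptic scaffold gene Bsn (0.10). Upper-layer neuron markers had a median of -0.09 with 1 of 13 higher, Mdga1 (0.56), and deep-layer markers had a median of -0.02 with 1 of 20 lower. Oligodendrocyte and myelin genes had a median of -0.08 with 0 of 29 past the threshold (camera adjusted p = 0.0911), and Opalin stood at -0.34. Choroid plexus and ependymal markers, which can enter with the dissected piece, had a median of 0.30 (camera adjusted p = 0.0861). Their mean log2 CPM lay above the WT mean in 10 of 10 HOM libraries (exact permutation, adjusted p = 0.14). Stress granule genes had a median of -0.01 with 1 of 14 higher and 1 lower, and oxidative phosphorylation genes 0.00 with 2 of 81 lower. Adjusted over the list alone, 1 stress granule gene was higher and 2 were lower, 1 upper-layer marker was higher, and 0 synaptic, deep-layer, oligodendrocyte, choroid plexus or oxidative phosphorylation genes passed. The median and the sign of the test or of the mean differed for axonal cytoskeleton genes (median -0.02), splicing factors (0.01), interferon-stimulated genes (0.05), the other interneuron markers (-0.04), red blood cell genes (-0.00234) and striatal markers (-0.03).

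**Figure D3:**
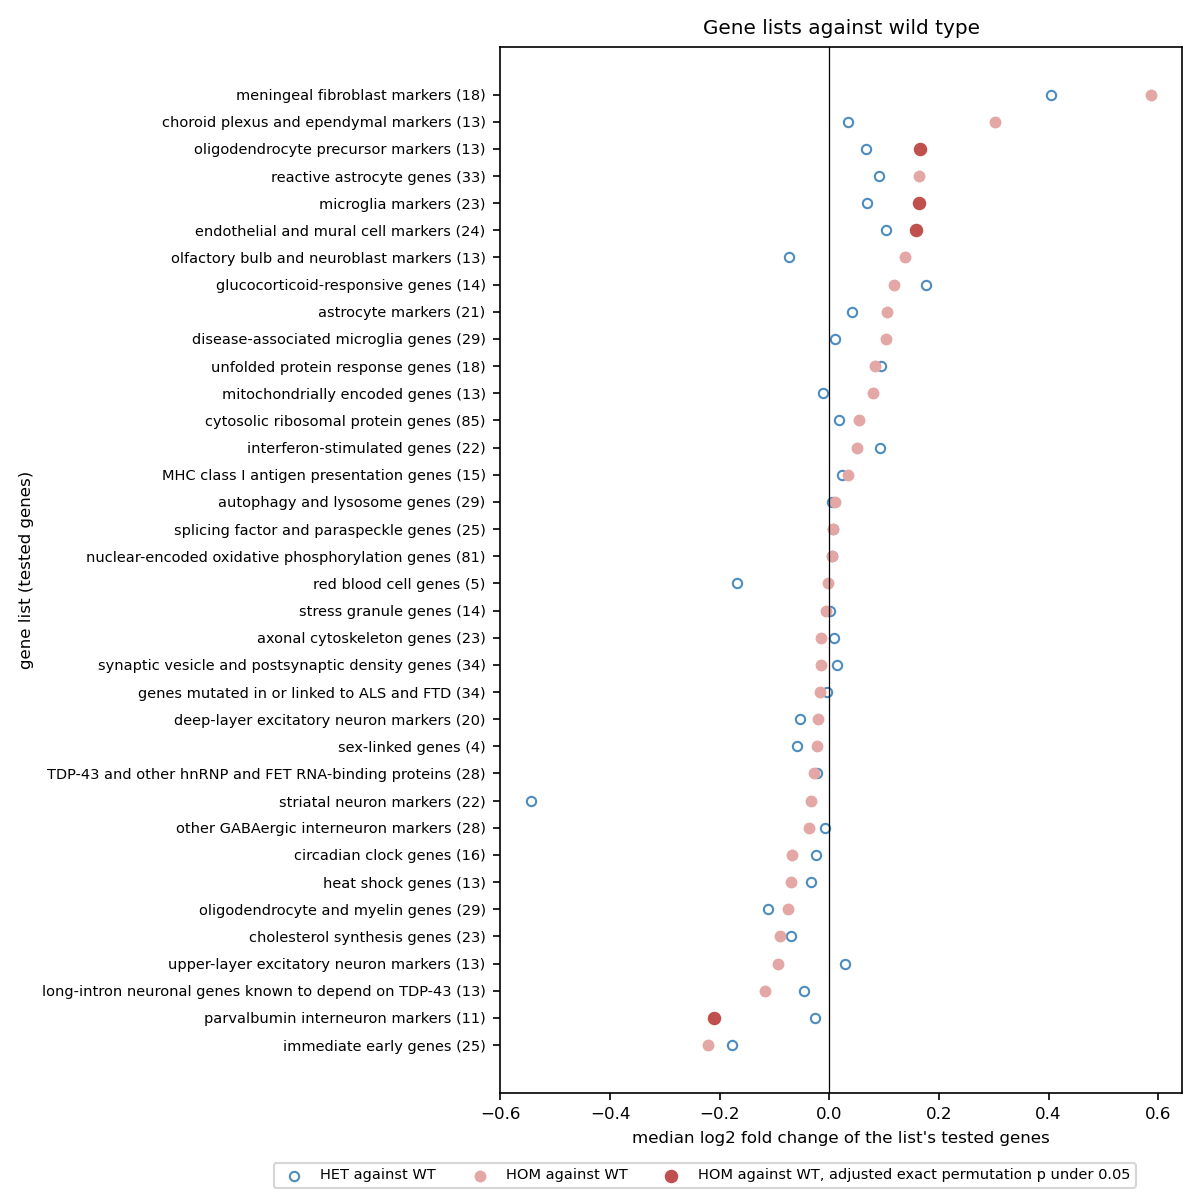
Median log2 fold change against WT of the tested genes of each of 36 lists, in HET (open circles) and HOM (filled circles), with the number of tested genes in brackets. Filled dark circles mark the 4 lists that passed exact permutation in HOM, at 0.17, 0.16, 0.16 and -0.21.

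The comparison of HET with WT asks what 1 mutant allele changes. The genes nearest the threshold were 4933439F18Rik, which averaged 72.4 ± 2.2 CPM in HET (n = 10) against 79.6 ± 2.45 in WT (n = 8), and Rragd, at 149 ± 7.17 against 169 ± 5.84. Both had an edgeR adjusted p of 0.0634, and both were picked after their values were seen. Tardbp differed by less than the spread between libraries. No gene passed by edgeR's quasi-likelihood test: the count was 0, and DESeq2 called 12 and limma voom 14. An unadjusted p under 0.05 was reached by 1547 genes, where 806 would be expected by chance if genes were independent. Genes move together across libraries, so this excess alone is not evidence of a change in HET. Camera with the preset correlation passed 14 lists, while 0 passed exact permutation and 0 passed with an estimated correlation. Meningeal markers had a median of 0.40 (adjusted p = 0.73 with an estimated correlation), endothelial and mural markers 0.10 (adjusted p = 0.721 with an estimated correlation) and striatal markers -0.54 (adjusted p = 0.73 with an estimated correlation).

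HOM and HET differed directly in 6 genes. D2hgdh (10.6 against 8.5 CPM) and Rlbp1 (26.8 against 22.6 CPM) were higher in HOM, and Spop, Pigk, Scg5 and 4933439F18Rik were lower. The log2 fold change of HOM over HET was 0.31 for D2hgdh, 0.24 for Rlbp1, -0.12 for Spop, -0.14 for Pigk, -0.15 for Scg5 and -0.30 for 4933439F18Rik. All 6 were also among the genes called between HOM and WT, but both comparisons use the same HOM libraries, so this overlap is partly built in. DESeq2 called 48 genes and limma voom 38. Microglia markers had a median of 0.12 and parvalbumin markers -0.09, each with adjusted p = 0.103 with an estimated correlation. Of 15 lists that passed camera with the preset correlation, 0 passed permutation. The count was 15 without HET 10, 12 without HOM 1, and 3 without any 1 of HET 2, HET 7, HOM 3, HOM 8 or HOM 10.

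Across the 3 genotypes, 1254 genes changed with the number of Q331K alleles (edgeR quasi-likelihood slope, adjusted p under 0.05), 643 upwards and 611 downwards. By smallest p, D2hgdh, Rlbp1 and Itgb5 led the rise and 4933439F18Rik, Spop and C030039L03Rik the fall, at -0.22, -0.11 and -0.11 per allele on the log2 scale. C030039L03Rik (reference name Zfp607b) belongs to a large family of similar zinc-finger genes, so its value is uncertain. In all, 1182 of these genes were also called between HOM and WT. The slope rests largely on the same WT and HOM libraries, at the ends of the scale. The overlap is therefore mostly built in and is not separate evidence of a dose response. Without WT 6 the count was 681. A departure from a straight line was called in 0 genes by edgeR, DESeq2 or limma voom. There, 456 genes had an unadjusted p under 0.05, below the 806 expected by chance if genes were independent.

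The genes that separated HOM from WT mostly had the same sign in HET, but both comparisons use the same 8 WT libraries. Among the 1226 genes with the largest statistic between HOM and WT, 98.4% had the same sign in HET, where 100 simulated draws of unchanged groups against the same controls gave 88.9% on average, with an upper limit of 97.6%. The median ratio of the HET to the HOM log2 fold change was 0.53, against 0.554 in the simulation. With the WT libraries split into sets of 4 so that no control was shared, it was 0.272 and 0.262 in the 2 arrangements, inside the simulated ranges with upper limits of 0.313 and 0.353. Across all tested genes, which are not independent replicates, the log2 fold changes correlated with r = 0.73 against 0.557 simulated, inside the simulated range of 0.395 to 0.736. Their covariance was 0.0138 against 0.00664 simulated, a difference of 0.00721, and lay above the simulated upper limit of 0.011. With no control shared, the covariance was 0.00744 and 0.0081, above simulated upper limits of 0.00472 and 0.00551. The correlation was then r = 0.288 and 0.334, above simulated upper limits of 0.257 and 0.27. With 0 genes called in HET, independent lists would share 0.

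Libraries of the same genotype were spread more widely in HOM than in WT, but not past the adjusted threshold. The mean variance of log2 CPM over the tested genes was 0.0587 in HOM, 0.0461 in HET and 0.0469 in WT. The ratio of HOM to WT was 1.25 (permutation test with 100000 resamples, two-sided, p = 0.0359, adjusted p = 0.0648 over 3 comparisons) and the ratio of HOM to HET was 1.27 (permutation, adjusted p = 0.0648). HET and WT had a ratio of 0.983 (permutation, adjusted p = 0.851). Over the 5000 genes with the highest counts the ratio of HOM to WT was 1.48 (permutation, adjusted p = 0.175). The mean squared distance to the rest of the group was 0.0915 for HOM 3 and 0.0741 for HOM 10. It was 0.083 and 0.0713 for HOM 1 and HOM 2, the shallowest libraries. The part of depth in this spread was not tested.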

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

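All of these values were found by looking for single libraries far from the rest of their group, and the tests of other glial and vascular markers and of synaptic genes elsewhere in this section were chosen after the results were seen. A library stood apart in 24 of 234 groups of 8 or 10 libraries, over 78 values. Chance marks about 1 in 20 groups.

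HET 10 held the highest HET values of Tardbp (358 CPM), Itgb5 (53.1 CPM) and Cbs (43.6 CPM) and the lowest of Acat2 (25.7 CPM). HET 9 was lowest in 4933439F18Rik (67.4 CPM), HET 3 lowest in Sod2 (108 CPM), HET 4 highest in Col1a1 (4.66 CPM) and HET 7 highest in Rgs5 (145 CPM). Among WT libraries, WT 4 was highest in Rlbp1 (24.4 CPM) and lowest in Grm8 (13.03 CPM), and WT 8 was highest in Olfml3 (18.2 CPM).

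HOM 9 was highest in Cbs (47.5 CPM), Glul (2515 CPM) and Mdga1 (31.7 CPM). HOM 10 was lowest in Sod2 (98.6 CPM) and Grm8 (11.3 CPM) and highest in Olfml3 (23.5 CPM). HOM 3 was highest in Vim (64.9 CPM, where the next HOM library held 37.7 CPM) and Aqp4 (177 CPM). HOM 1 and HOM 2, the shallowest libraries, stood apart in Scg5 (175 CPM), Asns (91.1 CPM) and Sst (219.3 CPM) for HOM 1, and in Pigk (71.0 CPM) and Rps15 (318 CPM) for HOM 2.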

How the results depend on the processing

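Settings with marker scores, without WT 6 and HOM 3, without HOM 1 and HOM 2, with numbers 1 to 8 only, and the permutation of list scores were chosen after the data were examined. Between HOM and WT, counts stayed within 1.5 times of 1226 with DESeq2 (1566), its size factors (1199), no filter (984), a stricter filter (1261), surrogate variables (1386), limma voom (1400), only these groups (832) and without HOM 1 and HOM 2 (876). They moved to 509 without WT 6 and HOM 3 and 393 with marker scores, where the SE grew. With numbers 1 to 8 the count was 636 without a block and 391 with the replicate block. Replicate numbers do not pair these libraries: correlations of same-numbered libraries ran from -0.158 to 0.126 for HOM and WT, -0.0476 to 0.183 for HET and WT and -0.164 to 0.134 for HOM and HET, and 0, 0 and 3 were best with their own number. For HET against WT, where the count was 0, it was 1 with the stricter filter, 12 with DESeq2, 5 with surrogate variables, 14 with limma voom, 4 with only these groups, 2 with numbers 1 to 8 and 2 without HOM 1 and HOM 2. Between HOM and HET (6) it was 48 with DESeq2, 38 with limma voom, 3 with surrogate variables, 2 with the block and 2 with marker scores. For allele number (1254) it was 608 without WT 6 and HOM 3 and 470 with marker scores, and for departure from a line 1 with surrogate variables. List calls for HOM against WT (14) were 0 with an estimated correlation, 6 with fry and 4 by permutation. For HET against WT (14) they were 0, 0 and 0, and 4 with marker scores, and for HOM against HET (15) 0, 3 and 0. The cause of these shifts was not tested. Tardbp kept its direction, at 0.11 with numbers 1 to 8 (edgeR adjusted p = 0.0566). Mapt, not called, turned to 0.00126 with marker scores, and Atxn2 to 0.00359 with the block and 0.0037 with numbers 1 to 8. The spread ratio of HET to WT was 1.07 over the 5000 genes with the highest counts.

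With each library left out in turn, the HOM and WT count ran from 595 (without WT 6) to 1345, and was 725 without WT 2. The allele number count ran from 681 (without WT 6) to 1401, the HET and WT count from 0 to 3 (1 without WT 1, HET 10, HOM 2, HOM 3, HOM 9 or HOM 10; 2 without WT 4 or HOM 1; 3 without HET 2 or HOM 8), and the HOM and HET count from 3 (without HET 2, HET 7, HOM 3, HOM 8 or HOM 10) to 15 (without HET 10), with 12 without HOM 1. The departure from a line stayed at 0. Lists ran from 12 to 17, 11 to 15 and 12 to 17, and Tardbp from 0.10 to 0.13. Of 1068 values of named genes under other settings, 902 kept direction and call, 144 lost the call, 19 gained it and 3 reversed. Values never called that stayed so count as kept. Settings differed: of 90 values each, 38 lost the call with marker scores, 28 with the replicate block and 24 without WT 6 and HOM 3. With DESeq2 or its size factors 0 did. Of 2520 values with a library left out, the counts were 2345, 153, 22 and 0. A sex covariate was not run, since every library shows the male pattern. At these depths, spreads and group sizes, 59.2% of simulated 1.3-fold changes between HOM and WT were recovered. For HET against WT, where the same genes were given the square root of that fold, it was 30.6%, and 8% at the smallest fold simulated. Other depths, and genes that move together, were not simulated, so these shares are not the power of the real tests.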

Other observations

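Among autophagy and lysosome genes, 3 of 29 rose in HOM against WT and 1 fell, with the same counts adjusted over the list alone and a median of 0.01 (camera adjusted p = 0.561). Grn, which encodes progranulin, went from 43.3 ± 1.74 CPM in WT (n = 8) to 47.7 ± 3.19 in HOM (n = 10), and 7 of 10 HOM libraries lay above the highest WT library. Among unfolded protein response genes 1 of 18 fell, Asns, from 88.2 ± 3.29 to 82 ± 3.69 CPM, and the list had a median of 0.08 (camera adjusted p = 0.561). The tests of other glial and vascular markers against microglia and of synaptic genes against long genes were chosen after those results were seen. The settings without HOM 1 and HOM 2 and with marker scores were also chosen after the data were examined.

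For the number of genes that differed between HOM and WT, chance is an unlikely source if the libraries are independent, which the labels do not say. Of 100 splits of the 18 libraries, 1, the real one, called as many genes (832 with only these groups in the fit, and at most 1 in any other split). With 100 splits the share cannot fall below 1 in 100. The shallow libraries are not the whole source of the difference, since without HOM 1 and HOM 2 the count was 876 and 743 of the 1226 genes were still called. With scores of meninges, striatum, myelin and choroid plexus as covariates the median absolute log2 fold change of the called genes was 92.2% of its value (0.17 before, 0.16 after), and the count fell to 393 as the median SE rose from 0.0437 to 0.0521. Of 229 tested genes within 10 Mb of Tardbp, 15 (6.55%) were called, against 7.62% elsewhere (Fisher's exact test, p = 0.617). So few genes there could not have been the main source of 1226 calls, whatever the test gave. The share called was not higher near the locus, but the test does not exclude a local excess. Effects of carried-over flanking sequence on genes elsewhere were not tested. Genotype, and litter and batch, which the labels do not give, all stay open, and no test here separates them.

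Microglia markers were higher in HOM, by 0.164 ± 0.0378 (SE) in mean log2 CPM. A lower share of neurons, which would raise markers of every other cell type alike, stays open: oligodendrocyte genes had a median log2 fold change of -0.0754 where microglia had 0.163, but the microglia score did not move apart from any of the 4 other glial and vascular scores by more than the spread between libraries (exact permutation, two-sided, smallest adjusted p = 0.143). With the meningeal and endothelial scores as covariates the difference was 0.0556 ± 0.0466, or 34.0% of its value, which is consistent with more meninges or vessels in the dissected piece of HOM cortex. The endothelial score itself differed between the genotypes, so a change of vessels and microglia together may give the same value. The number of list calls does not settle it either: 44 of 100 splits gave at least the 14 lists that camera passed, and the highest other split gave 23, so chance cannot be excluded for that count.

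Long genes leaned lower in HOM: of called genes spanning at least 100 kb, 155 were lower and 72 higher, against 442 lower and 557 higher among other called genes. Over all 2259 long genes the difference from other genes in mean log2 CPM was -0.02 (exact permutation, two-sided, p = 0.0979), and -0.01 among genes not called (p = 0.364, exact permutation). A bound on p had been set beforehand to exclude an effect of length, but a p that misses a threshold does not show that values were alike, so that bound was set aside. Within deciles of exon length 23.1% of the difference was left (exact permutation, p = 0.581), and the synaptic list, which stands for neurons, had a median log2 fold change of -0.0159. A loss of long transcripts, transcript length and fewer neurons cannot be told apart here, because the difference itself is within the spread of the libraries.

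Other splits were also drawn for the remaining counts. For HET against WT 1 of 100 splits gave as many genes (4 with only these groups, highest other 1), for HOM against HET 1 of 100 (6, highest other 3), and for allele number 1 of 100 (1254, highest other 126). For the departure from a straight line the real count was 0, so all 100 of 100 assignments gave at least as many and the comparison says nothing on chance. Another 9 assignments called genes, at most 213, which may point to a structure among the samples, and its source was not tested.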
